A study of Zea mays with 58 samples.

How the data were processed

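Roots of maize seedlings of the inbred line B73 were profiled by 3' mRNA sequencing, a method in which each transcript gives reads near its polyadenylated end, with a unique molecular identifier (UMI) that marks each captured molecule. Seedlings were 10 days old and had been kept without nitrogen for 2 days before the transfer, per the labels' protocols. They were moved to medium with 20 mM KNO3 and 20 mM NH4NO3 (N) or with 20 mM KCl (noN). Roots were taken every 5 min up to 20 min, then at 30, 45, 60, 90 and 120 min, in both media and at time 0 in noN only. Each replicate pooled 3 seedlings. The 58 libraries fall into 19 groups of 3, apart from noN at 120 min with 4. Libraries were sequenced as single reads of 75 bases.

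Per the submitters' processing notes, the tools were UMI-tools 1.1.1, fastp 0.21.0, STAR 2.7.6a and featureCounts 2.0.1. Per the file headers, the authors' deposited table holds whole-number counts per gene, counted on the sense strand against release 37 of the AGPv4 annotation, and the command line recorded there does not set the option that counts reads with several alignments. Reads of near-identical gene copies are therefore left out or, where only some of their positions differ, uneven between copies, and no genome was used here to find such genes. The counts were used as deposited. The table has 46335 features and every library has its own column. Totals per library ran from 1978039 to 3790442 counts with a median of 2617921.

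The authors' deposited second table holds quantile normalized expression, a score rounded to whole numbers, for 18616 genes in 57 libraries. Replicate 4 of noN at 120 min is the library it leaves out, and every library in it sums to 2577142. The authors' deposited network table holds a score of at least 0, the weight, for each of 449624 pairs of 196 regulators and 2294 targets. How the weights were made is not given in the sources used here.

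Genes were kept by filterByExpr over the 19 groups (minimum count 10, minimum total 15), which left 18872 genes with 99.7% of the counts. Libraries were scaled by TMM. One quasi-likelihood model of edgeR 4.0.16 (R 4.3.3), with 1 mean per group and 39 residual degrees of freedom, gave all main results. From the dispersion estimation this fit takes the trended dispersion, and its quasi-likelihood step then estimates a further spread for each gene. Leaving out the gene-wise step of the dispersion estimation was checked to give equal values of that spread. The contrasts were any N effect over the 9 times (joint test), the mean N effect over the 9 times, the N effect at each time, the N by time interaction, the mean N effect at 60, 90 and 120 min minus that at 5, 10 and 15 min, any change over time in noN, and noN at 30 and at 120 min against time 0. These were fixed before the data were examined. The mean N effect at 60 to 120 min, the steps between neighbouring times and the changes from time 0 or from N at 5 min were added after the libraries had been seen. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p of 0.05. Fold changes are on the log2 scale with their standard errors (SE). Values per library are CPM (library-scaled counts) with TMM scaling, and principal components used log2 CPM with a prior count of 3. In joint tests the direction of a gene is that of its mean coefficient.

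The model was tested on simulated data drawn from the real means and library sizes, with 200 changed genes among 18872. Each gene had the trended dispersion of the fit, a mean constant over time and, if changed, the same fold change in every N group. Extra spread of single genes and effects that vary with time were not simulated, so the shares that follow can be too high for the real data. They can also be too low, since the Benjamini-Hochberg cutoff is stricter with 200 changed genes than where more genes change. For the N effect at 60 min, 10.4% of 67 genes changed 1.5-fold, 37.3% of 67 changed 2-fold and 87.9% of 66 changed 4-fold were recovered, with 5 false calls. For the mean N effect over 9 times the shares were 85.1%, 95.5% and 100%, with 7 false calls. For the joint test they were 73.1%, 91.0% and 98.5%, with 7 false calls.

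The count table identifies genes by ID. The reference table of gene names is of another assembly, so none of its coordinates were used; 153 features matched it, none of them among the genes tested, and 0 of the 44146 gene model IDs (Zm00001d) matched. The 25 gene lists fixed before the data were examined consequently have 0 members and were not tested. The rule fixed for named genes allows at most 2 IDs that rose and 2 that fell where no names exist; they are the risen and the fallen IDs with the smallest p of the joint test among those with a log2 fold change of at least 1 at some time and a mean effect of that sign. Other genes are described as groups, by genomic region or by class. Coordinates are those of the count table (AGPv4), from the first to the last exon base.

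Replicates of a group differed beyond sampling noise: the chi-square statistic of a pair, per gene with at least 20 counts in the pair, was at least 2.15, with a median of 5.45, where sampling noise alone gives 1, so all libraries were kept as separate replicates. Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter, a minimum log2 fold change of 1, the replicate number as a block, a fit of a single time point, a natural cubic spline of time, limma 3.58.1 on log2 of the quantile normalized score plus 1, and each library left out in turn. Removal of each library's trend with gene length, thinning of all libraries to the lowest total, and subsets of the times were added after seeing the data. Other splits of the libraries were drawn with fixed seeds. Shoots, also collected per the labels' protocols, were not analysed here.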

Results

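Root transcripts were counted in 58 libraries from nitrogen-starved B73 maize seedlings that were moved to medium with nitrate and ammonium (N) or with potassium chloride in their place (noN). The series samples the first 120 min after this transfer, and each N group has a noN group of its own time. The N effect is therefore a difference between the media at equal time. The media also differ in chloride and in total salt, with 20 mM KNO3 and 20 mM NH4NO3 against 20 mM KCl. The N effect is not separated from these differences. Every group holds 3 biological replicates, apart from noN at 120 min with 4. Library totals were between 1978039 and 3790442 counts, and 18872 genes were tested. The counts carry gene model IDs and no gene names, so the responses are described through groups of genes, their time courses, their class and their place in the authors' network, with 4 IDs in full.

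The N effect is given first for 60, 90 and 120 min, where the counts of N and noN libraries fell on genes of like length. Averaged over these 3 times, 2804 genes were higher and 3188 were lower in N than in noN roots (edgeR quasi-likelihood test, adjusted p of 0.05). The balance was the other way in limma on the authors' quantile normalized values, with 3173 higher and 2946 lower. Of the edgeR calls, 527 genes were higher by at least 1 on the log2 scale and 760 were lower by as much. The strongest responses reached beyond a log2 fold change of 4, in 23 genes that were higher and 16 that were lower. This average was added after the libraries had been seen, because the earlier times compare libraries that differ in makeup.

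Zm00001d034345 (AGPv4 chromosome 1, 290272584 to 290276056, minus strand, exon length 2347 bases) rose early and far. In N roots it went from 80.8 ± 6.64 CPM (SD, n = 3) at 5 min to 168 ± 53 at 10 min, 417 ± 47.4 at 15 min and 2698 ± 80.2 at 60 min. In noN roots it stood at 65.9 ± 6.91 CPM at time 0, at 99.7 ± 21.8 at 45 min, at 149.7 ± 49.6 at 60 min and at 110.1 ± 23.4 (n = 4) at 120 min. The N effect was 1.05 (SE 0.23, edgeR adjusted p = 0.001877) at 10 min and 4.53 (SE 0.22, edgeR adjusted p = 1.02e-20) at 120 min. At 5 min the difference of 0.38 (SE 0.23) did not pass the test (edgeR adjusted p = 0.4028).

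Zm00001d025015 (chromosome 10, 99806303 to 99812704, plus strand, exon length 4835 bases) first passed the test at 15 min. It was at 18.7 ± 2.38 CPM (SD, n = 3) in N roots at 5 min and at 19.3 ± 3.55 at 10 min, then at 37.3 ± 5.78 at 15 min, 261 ± 61.3 at 30 min and 703 ± 105 at 90 min, and it had come down to 377 ± 28.9 at 120 min. Its noN groups had means between 11.9 and 22.3 CPM throughout. The N effect was 1.45 (SE 0.21, edgeR adjusted p = 1.794e-06) at 15 min and 5.09 (SE 0.22, edgeR adjusted p = 5.461e-23) at 60 min, 34.2-fold. For both genes every N library from 15 min on lay above every noN library of the series.

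Both IDs that the rule gave as fallen had N effects of opposite sign before and after the step from 45 to 60 min. At that step the makeup of the noN libraries also changes, as described with the gene lengths. The sign changes, and the effects at 5 to 45 min, cannot be told apart from that difference. The joint test that chose both IDs also spans that step. Zm00001d006639 (chromosome 2, 213114825 to 213115853, plus strand, exon length 884 bases) was higher in N roots at 5 min by 1.00 (SE 0.25, edgeR adjusted p = 0.01405). Its difference at 45 min, 0.26 (SE 0.26), did not pass the test (edgeR adjusted p = 0.4886), and it was lower at 60 min by a log2 fold change of -2.23 (SE 0.25, edgeR adjusted p = 9.629e-09). In noN roots it moved from 9.08 ± 1.33 CPM (SD, n = 3) at 45 min to 30.5 ± 6.54 at 60 min, while in N roots it went from 11 ± 2.05 to 6.41 ± 1.17. Its mean effect over 9 times was -0.07 (SE 0.08), which did not pass the test (edgeR adjusted p = 0.5205). Zm00001d027484 (chromosome 1, 6296235 to 6300940, minus strand, exon length 4193 bases) was lower in N roots at 20 min by -1.16 on the log2 scale (SE 0.16, edgeR adjusted p = 8.947e-07) and at 45 min by -0.97 (SE 0.16, edgeR adjusted p = 1.609e-05). Its difference of 0.48 (SE 0.16) at 60 min did not pass the test (edgeR adjusted p = 0.09552), and it was higher at 90 min by 0.64 (SE 0.16, edgeR adjusted p = 0.004781). Its noN level dropped from 162 ± 11.7 CPM at 45 min to 71.2 ± 7.29 at 60 min. No genome was used here to see whether any of the 4 shares reads with a near-identical copy.

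**Figure D1:**
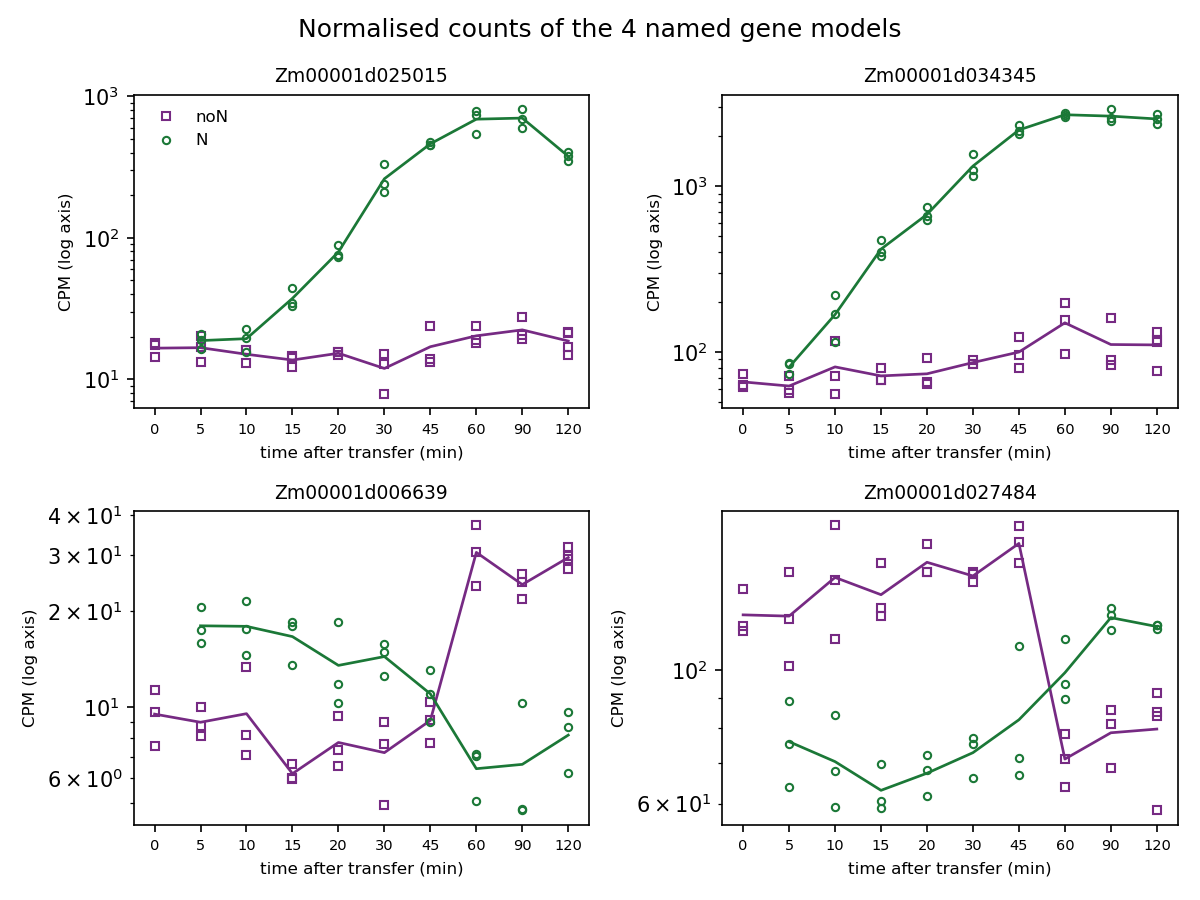
Normalised counts (CPM, log axis) of the 4 named gene models against time after transfer, with each library as a point and group means as lines, N in green circles and noN in purple squares. In N, Zm00001d034345 reached 2698 CPM at 60 min and Zm00001d025015 703 CPM at 90 min, against noN group means of at most 149.7 and 22.3 CPM, and Zm00001d006639 and Zm00001d027484 show the noN levels moving between 45 and 60 min, from 9.08 to 30.5 and from 162 to 71.2 CPM.

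Of the 527 genes higher in N, 263 had risen and 24 had fallen in N roots between time 0 and 90 min, and in noN roots 52 had risen and 135 had fallen. Their median change from time 0 in N was 0.14 at 30 min, 0.83 at 60 min and 1.19 at 90 min (interquartile range 0.44 to 2.26). In noN the median at 90 min was -0.40 (interquartile range -1.32 to 0.49). Within N roots alone, 28 of these genes had been called above their 5 min level by 15 min, 117 by 30 min, 210 by 60 min and 303 by 120 min. These counts add up first calls and keep genes that came back down. At 30 min itself 117 were above and 29 below the 5 min level, at 60 min 208 and 37, and at 120 min 253 and 8. At times not used to choose them, 114 of the 527 were higher and 23 were lower in N than in noN at 15 min, 168 and 6 at 30 min, and 238 and 3 at 45 min. Over all 18872 tested genes these counts were 2783 and 2353 at 15 min, 2300 and 1497 at 30 min, and 2529 and 1929 at 45 min. All contrasts at these times compare libraries that differ in makeup, as described with the gene lengths.

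Of the 760 genes lower in N, 444 had risen and 1 had fallen in noN roots between time 0 and 90 min, and in N roots 35 had risen and 70 had fallen. Their median change from time 0 in noN was 1.09 at 60 min and 1.78 at 90 min (interquartile range 1.01 to 2.57). In N the median at 90 min was -0.08 (interquartile range -0.67 to 0.53). At 15 min the noN median already stood at 1.15 with 246 risen and 20 fallen, and it was back to 0.67 at 20 min with 19 risen and 7 fallen. At times not used to choose them they went both ways: 72 of the 760 were higher and 188 were lower in N than in noN at 15 min, 85 and 120 at 20 min, 76 and 38 at 30 min, and 40 and 52 at 45 min. Over all 18872 tested genes these counts were 2783 and 2353 at 15 min, 3094 and 2613 at 20 min, 2300 and 1497 at 30 min, and 2529 and 1929 at 45 min. These contrasts too compare libraries that differ in makeup. Both groups were chosen on the 60 to 120 min libraries, so their values at those times are not independent of the choice, and the 2 arms share the 3 time 0 libraries, which belong to the 21 libraries of differing makeup described with the gene lengths. The median of all other genes stayed between -0.03 and 0.02 in every one of these comparisons.

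**Figure D2:**
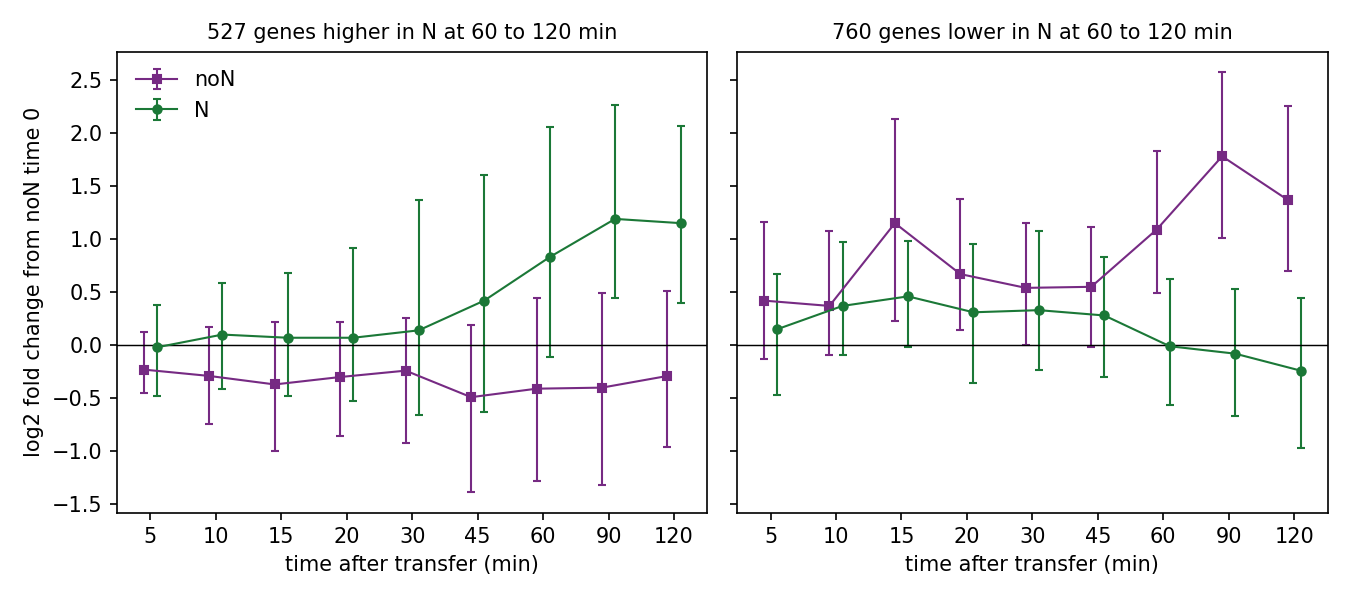
Median log2 fold change from noN time 0, with bars for the interquartile range over genes, against time after transfer in N (green) and noN (purple), for 527 genes higher and 760 genes lower in N at 60 to 120 min. The median of the first group is 1.19 in N at 90 min, and that of the second is 1.78 in noN at 90 min and -0.08 in N.

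At single times, the N effect involved 680 genes at 5 min (497 higher, 183 lower), 2215 at 10 min (1427 and 788), 5136 at 15 min (2783 and 2353) and 5707 at 20 min (3094 and 2613). It involved 3797 genes at 30 min (2300 and 1497), 4458 at 45 min (2529 and 1929), 771 at 60 min (471 and 300), 3222 at 90 min (1432 and 1790) and 2618 at 120 min (1144 and 1474). The contrasts at 5 to 45 min compare libraries that differ in makeup, as described with the gene lengths. The course of these counts is therefore not one of the N effect alone. Fits of a single time point called 452 genes at 5 min, 768 at 10 min, 3758 at 20 min, 2248 at 30 min and 1439 at 120 min, each under the shared fit by over 1.5 times. At 10 min limma on the authors' quantile normalized values, another test on another table of 57 libraries, gave 1182 higher and 1130 lower genes, while DESeq2 size factors in edgeR gave 1407 and 816. The limma fit also turned the balance at 20 min (2611 higher and 2669 lower), 45 min (2200 and 2284) and 90 min (1846 and 1760). Single libraries decided part of these counts: without replicate 2 of noN at 5 min 247 genes were called at that time, without replicate 2 of N at 10 min 902, without replicate 2 of N at 60 min 377, and without replicate 3 of noN at 90 min 1634.

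**Figure D3:**
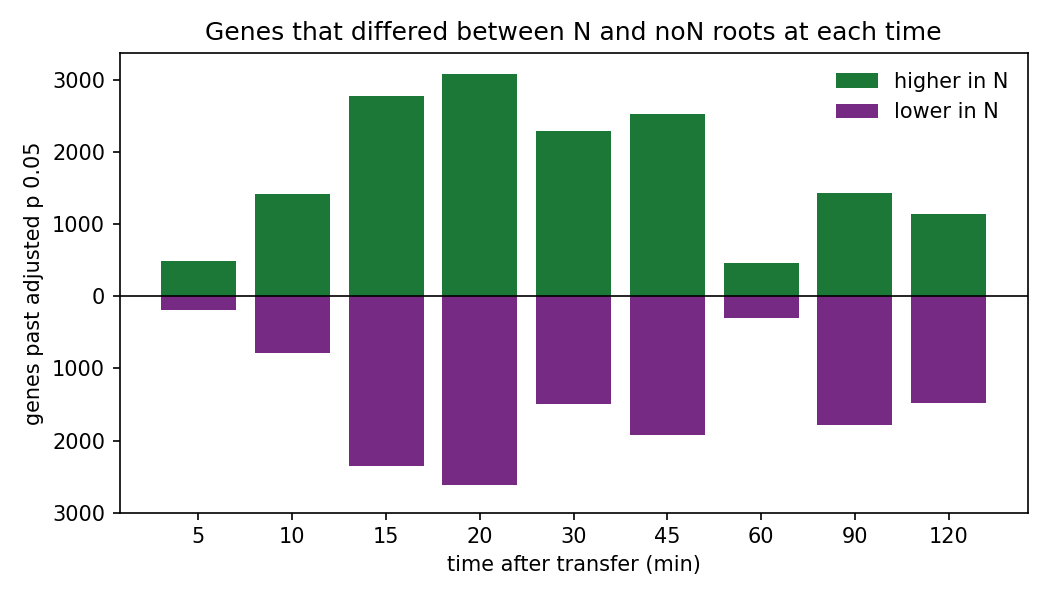
Genes past an adjusted p of 0.05 in the N against noN contrast at each time after transfer, with genes higher in N above 0 and genes lower in N below it. The counts climb to 5707 at 20 min and stand at 771 at 60 min.

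At any of the 9 times, 11626 of 18872 genes (61.6%) differed between N and noN, and 5853 of them did so by at least 1 on the log2 scale at some time. The mean over the 9 times differed in 9843 genes, 4825 higher and 5018 lower, of which 975 reached a log2 fold change of 1. Restricted to 60, 90 and 120 min the joint test called 4939 genes, and restricted to 5 to 45 min it called 9818.

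The N effect changed with time in 7496 genes (N by time interaction) and differed between 60 to 120 min and 5 to 15 min in 7678 genes, 3565 in the positive and 4113 in the negative direction. Far fewer genes were called inside either period than between them. The tests inside a period are joint tests over single times, while the 7678 genes come from a contrast of averages, so the counts are not of like tests. Within 5 to 45 min the interaction called 413 genes, and within 60 to 120 min it called 108. Across genes, which are not independent replicates, N effects at 2 times correlated at 0.49 to 0.78 within 5 to 45 min, at 0.56 to 0.69 within 60 to 120 min and at 0.12 to 0.35 between these periods. Of the genes called in the means of both periods, 827 were higher in both, against 833 for independent lists of those sizes, and 660 were lower in both, against 995. A further 1419 went from higher to lower, against 947, and 1006 from lower to higher, against 876. The means of the 2 periods share no library.

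The break coincides with a difference between libraries. The 21 noN libraries of 0 to 45 min carried their counts on longer genes, with a count-weighted mean log2 exon length of 11.05 ± 0.032 (SD, n = 21), against 10.98 ± 0.016 (n = 18) in N at 5 to 45 min, 10.99 ± 0.005 (n = 9) in N at 60 to 120 min and 10.99 ± 0.012 (n = 10) in noN at 60 to 120 min. The lowest of the 21 was at 11.01 and the highest of the other 37 at 10.999. The 50 most counted features took 7.96% ± 0.70 of their counts, against 10.2% ± 0.68, 9.10% ± 0.61 and 9.31% ± 0.71. The 21 libraries were not alike in this. At time 0 the share was 8.99% to 9.59%, inside the range of noN at 60 to 120 min (8.25% to 10.66%). Their length measure also differed by time, from 11.029 to 11.034 at time 0 and from 11.078 to 11.114 at 45 min. The labels give no batch, so no fit with a batch term could be made, and at 5 to 45 min every N against noN contrast compares these 2 kinds of library. The single time contrasts at 5 to 45 min are given with that limit, as are the interaction, late minus early, the results over all 9 times and every noN or time 0 comparison that spans 45 to 60 min.

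**Figure D4:**
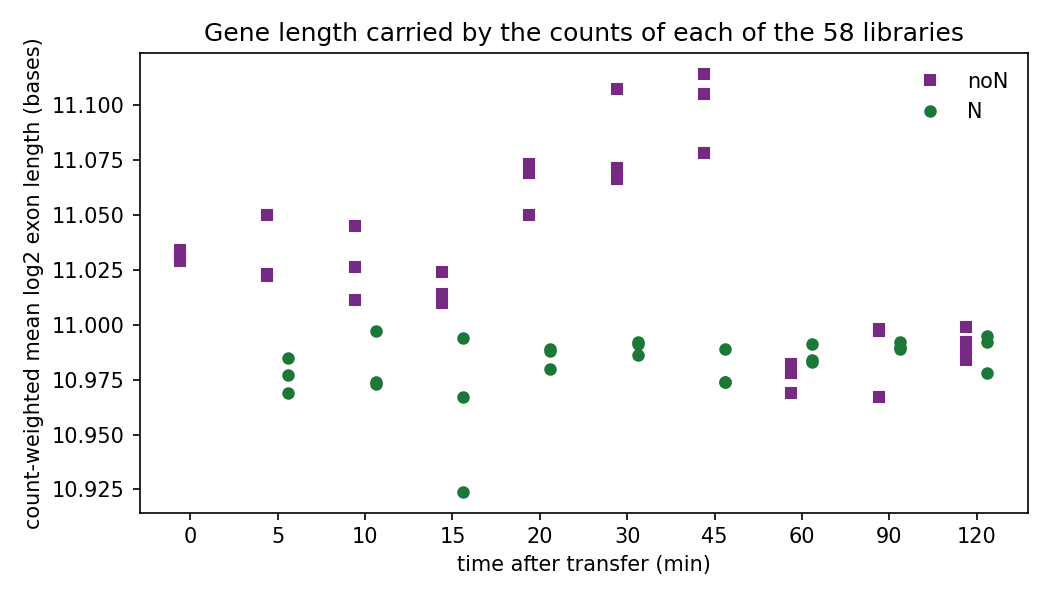
Count-weighted mean log2 exon length (bases) of each of the 58 libraries against time after transfer, N as green circles and noN as purple squares. The 21 noN libraries of 0 to 45 min lie at or above 11.01 and the other 37 at or below 10.999.

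Without nitrogen, 10800 genes changed over the 10 times; the libraries of 0 to 45 min and of 60 to 120 min differ in makeup, so this count is not one of the transfer and the passing time alone. Against time 0, 461 genes were higher and 879 lower at 30 min, and 3336 were higher and 2970 lower at 120 min. The 30 min count fell to 498 without replicate 2 of noN at 30 min, to 570 without replicate 2 and to 805 without replicate 3 of noN at time 0. No gene differed between 0 and 5 min in edgeR (1373 at an unadjusted p of 0.05). Between 10 and 15 min 417 genes rose and 62 fell, and between 15 and 20 min 115 rose and 387 fell. In N roots the same steps called 11 risen and 0 fallen genes and 1 risen and 0 fallen; the difference between the arms was not tested for these steps. From 45 to 60 min 2306 genes rose and 1937 fell in noN, against 3 and 2 in N, and the difference between these steps was called in 2064 genes. Restricted to 0 to 45 min the noN course called 3438 genes, and restricted to 60 to 120 min 467.

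Annotated non-coding RNA genes, those with an ENSRNA identifier, were mostly higher in N when all times were averaged. Over the mean of 9 times 88 of the 120 tested were higher and 1 was lower in N (median 0.57). At 60 to 120 min 4 were higher and 9 lower (median -0.12, and 0.04 in limma on the quantile normalized values). In noN roots 51 were higher and 1 was lower at 120 min than at time 0 (median 0.96). From 45 to 60 min in noN 27 rose and 1 fell (median 0.79). At 30 min against time 0 in noN 0 were higher and 0 lower (median -0.06). The mean of 9 times and noN at 120 min against time 0 both span the change in makeup of the noN libraries. The lean towards N in that mean cannot be told apart from this change. With each library's gene length trend removed, 32 were higher and 7 lower over the mean of 9 times (median 0.19). At 60 to 120 min 3 were then higher and 18 lower in N (median -0.23). In noN at 120 min against time 0, 29 were then higher and 4 lower (median 0.47). This setting was added after seeing the data.

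Nearly every gene that the authors placed in their network differed between N and noN at some time. In the authors' deposited table, 196 regulators are paired with 2294 targets, and all 196 regulators are also listed as targets. Of the regulators 194 differed between N and noN at some time, and 144 of these did so by at least 1 on the log2 scale; at 60 to 120 min 53 were higher and 114 were lower in N. Of the 2294 targets 2272 differed at some time, and at 60 to 120 min 820 were higher and 938 lower. The share of targets called at any time was 99.0%, against 56.4% of the other genes tested (odds ratio 79.8), and at 60 to 120 min it was 76.6% against 25.5% (odds ratio 9.56). Over the mean of 9 times the regulators leaned the other way, with 112 higher and 28 lower in N. The table comes from the same study of these roots, so these shares are not independent evidence of a response.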

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

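The tests of the length trend, of a shared event and of a fixed library difference, whole or in part, were chosen after the change between 45 and 60 min had been seen; the counts of other splits were set down before they were run. The mean at 60 to 120 min is itself a result added after the libraries had been seen. Nitrogen effects differed between times in 7496 genes by the interaction, and between 60 to 120 min and 5 to 15 min in 7678 genes. The change from 45 to 60 min differed between the arms in 2064 genes.

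The pattern weighed is that noN libraries changed between 45 and 60 min in 4243 genes. With 1 noN library of 45 and 1 of 60 min left out, 2099 to 3070 genes were called over 9 choices. Over longer spans N libraries changed as well, in 4456 genes from 5 to 120 min. The tables argue against 2 explanations. With each library's gene length trend removed the step still called 3564 genes. An event that moved all seedlings alike would move N roots, where the step from 45 to 60 min called 5 genes. The N step correlated with the noN step at -0.005 across genes. These values cannot speak to an event that brings roots to a state that N roots already had. N at 5 min minus noN at time 0, which shares no library with the noN step, correlated with that step at 0.409 across genes. The same difference moved 85.3% of the 4243 genes in the direction of the step. A fixed difference between the noN libraries of 0 to 45 min and all others could therefore account for part of the change. It would be the whole only with an opposing response of N roots within 5 min, which no table excludes: with 1 noN library of 45 and 1 of 60 min left out of the choice of genes, the median step in that pair was 0.63 to 0.81 over 9 choices, in each above every N 5 min library minus every noN library of time 0 (at most 0.46) or of 5 min (at most 0.59). Whether the fixed part is an unrecorded batch or a response within 5 min of nitrogen that noN roots reached at 60 min stays open, as does a drift in noN, where the same genes had moved the other way by a median of -0.2 from 0 to 20 min and -0.216 from 0 to 30 min, in libraries that took no part in choosing them.

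Other splits of the same libraries were counted for each result. Labels were split within times for any time, the mean, the interaction, late minus early and the mean at 60 to 120 min. In each, 1 of 60 splits, the real one, gave as many genes. The highest of the others were 1992, 0, 2488, 1 and 740 against 11626, 9843, 7496, 7678 and 5992. The splits for the mean at 60 to 120 min moved labels at the earlier times as well. Mixed groups at those times can widen the spread that all contrasts share and so lower the counts of the other splits. The 740 is therefore not a count for labels at 60 to 120 min alone, and it cannot exclude chance labelling there. The rest also take their effects from times before 60 min. There the noN label coincides with the libraries of differing makeup described with the gene lengths. Other splits there mix both kinds of library, so these counts cannot separate nitrogen from that difference. For the noN course and noN at 120 min against time 0, libraries were split across times. The real split was again the only one with as many genes (1 of 60, 10800 against 2662, and 1 of 35, 6306 against 4522). Those times span the change in makeup, so passing time is not separated from it. Chance labelling can be excluded at 120 min, where only the labels of that time were split (1 of 35, 2618 against 1580). At the other times and for noN at 30 min against time 0 the 10 splits are too few for a share under 0.05; the real counts were 680, 2215, 5136, 5707, 3797, 4458, 771, 3222 and 1340, and the highest of the others 0, 52, 0, 2, 0, 0, 1, 38 and 0.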

How the results depend on the processing

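The gene length trend, thinning and the subsets of times were chosen after seeing the data; the other settings were fixed before the data were examined, though not for the mean at 60 to 120 min and the values of named IDs at those times, which were added later. DESeq2, DESeq2 size factors in edgeR, no filter, the length trend removed and thinning to the lowest total each kept all 17 counts within 1.5 times; so did limma on the quantile normalized values for the 13 counts it was run on and the spline of time for 2. The 4 named IDs kept their direction and their calls at 60 to 120 min under every setting run. Over all times the replicate numbers did not clearly pair the samples: of 27 same-numbered N and noN pairs 7 correlated above 0.1 (range -0.288 to 0.255), and 10 correlated best with their own number. At 10 min the pairs stood at 0.14, 0.025 and 0.155, each best with its own number. At 90 min they stood at -0.152, -0.061 and -0.142, none best with its own. A replicate block kept all 17 counts within 1.5 times, 2257 genes at 120 min against 2618. This block is shared over all times and cannot test pairing within a time.

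A log2 fold change of at least 1 lowered every count by its construction: to 5853 for any time, 975 for the mean over 9 times, 1287 for the mean at 60 to 120 min, 3938 for the interaction, 2547 for late minus early, 4792 for the noN course, 608 and 2635 for noN at 30 and 120 min against time 0, and 281, 697, 2296 and 2523 for the N effect at 5, 10, 15 and 20 min, 1536 and 1849 at 30 and 45 min, and 427, 1476 and 1161 at 60, 90 and 120 min. Fits of one time point, which have fewer residual degrees of freedom, gave 452, 768, 3758, 2248 and 1439 genes at 5, 10, 20, 30 and 120 min. Subsets of the times moved the counts both ways: 5 to 45 min gave 11501 genes for the mean, above the 9843 of all 9 times, while 60 to 120 min gave 4939 genes for any time, 5992 for the mean, 108 for the interaction and 467 for the noN course; 5 to 45 min gave 413 for the interaction, and 0 to 45 min gave 3438 for the noN course.

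Leaving out 1 library gave 11131 to 11840 genes for any time, 9525 to 10112 for the mean, 5312 to 6104 for 60 to 120 min, 6836 to 7709 for the interaction, 7279 to 7781 for late minus early, 10131 to 10834 for the noN course, 498 to 1187 for noN at 30 min and 4704 to 6223 for noN at 120 min against time 0. Single times ranged over 247 to 464 genes at 5 min, 902 to 2743 at 10, 3673 to 4684 at 15, 3653 to 5465 at 20, 2556 to 3239 at 30, 2799 to 4033 at 45, 377 to 710 at 60, 1634 to 3387 at 90 and 1375 to 2600 at 120 min. Beyond the libraries named with the results, counts moved over 1.5 times without replicates 1 of N (1382) and 3 of noN (946) at 10 min, replicate 3 of N at 20 min (3653), replicates 1 of noN (2799) and 2 of N (2955) at 45 min, and replicates 2 (1375) and 3 (1716) of N at 120 min. At 5 min this held for replicates 1 (410) and 3 (369) of noN and 2 (397) and 3 (288) of N, at 60 min for replicates 1 (419) of N and 1 (471) and 3 (426) of noN, and at 90 min for replicate 3 of N (1869); the cause was not tested. At these depths the N effect at 60 min recovered 37.3% of 67 simulated 2-fold changes, with 200 genes changed. The share of network targets called at any time was 98.7% among the tenth of pairs with the highest weight, against 99.0%. The 25 gene lists have 0 members with a name, so their tests were not run.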

Other observations

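The tests of edge weights against expression level, and against the nitrogen response at equal level, were chosen after the result had been seen; those of neighbouring genes and of unadjusted edge weights against the nitrogen response were set down before it.

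Among the genes that differed at 60 to 120 min by at least 1 on the log2 scale, 7 runs of 3 neighbouring tested genes on a chromosome shared a direction, 4 higher and 3 lower in N. Neighbouring means next in order among the tested genes, so untested features can lie between them. Of the 7 runs, 3 span at most 100 kb as rounded. Chromosome 2 holds the tightest, 3 annotated genes within 7.2 kb (AGPv4 6886753 to 6893936) that were higher in N by 1.46 to 2.63 (largest edgeR adjusted p = 3.614e-05), though the ranges of mean log2 CPM overlapped, 3.22 to 7.05 in N and 2.31 to 4.95 in noN libraries at 60 to 120 min. On chromosome 10, 3 tested genes of 7 annotated features between 147240629 and 147354799 were higher by 1.45 to 4.20 (largest edgeR adjusted p = 8.27e-05), and every N library at 60 to 120 min, with a mean log2 CPM of at least 5.11, lay above every noN library, at most 3.91. On chromosome 6, 3 tested genes of 5 between 33061939 and 33369350 were lower by -1.30 to -2.93 (largest edgeR adjusted p = 0.01251), though their N and noN libraries approached each other at 4.01 and 4.21. On chromosome 4, 3 adjacent genes within 21.9 kb (10532759 to 10554681) were lower by -1.01 to -2.53 (largest edgeR adjusted p = 0.04755), with libraries overlapping at 4.03 to 4.78 in N and 4.08 to 7.30 in noN. These regions were chosen after their values were seen.

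Shuffling the calls over the 18736 tested genes on chromosomes gave a median of 1 and at most 6 such runs in 1000 shuffles, against the 7 observed. The 7 runs are consistent with the hypothesis that neighbouring genes respond together. Tandem copies that share reads could also give such runs; this was not tested, since no genome was used here, and the counting left out reads with several alignments.

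A group of 233 genes was higher in noN at 15 min than at both 10 and 20 min. Relative to time 0 their mean stood at 1.13 to 1.97 on the log2 scale in the 3 noN libraries at 15 min, from which they were chosen, and at 0.10 to 0.49 in the N libraries at 15 min. Outside 15 min the mean exceeded 1 in replicate 1 of noN at 5 min (1.22, against 0.01 and 0.03 in replicates 2 and 3), replicate 3 of noN at 60 min (1.01) and replicate 2 of noN at 90 min (1.1). No N library outside 15 min exceeded 0.31.

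Replicate 4 of noN at 120 min, which the authors' quantile normalized table leaves out, lay apart from the other 3 noN libraries of that time on 2 principal components, though none of the 12 measures of these 4 libraries passed Dixon's test. On the first principal component it stood at 40.59, against 1.75 to 19.57 for the other 3 and 30.21 to 32.32 for the N libraries, on the second at 10.86, against 37.7 to 47.36 and 19.74 to 26.23, with gaps of 0.541 and 0.735 of the range, both under the 95% critical value of that test. Its TMM factor, not among the 12, was 0.909, against 0.997 to 1.037 in the other 3. On a scale set by 745 responding genes, where the noN mean at 60 and 90 min is 0 and the N mean is 1, it stood at 0.02, against -0.06 to 0.01 for the other 3 noN and 0.97 to 1.04 for the 3 N libraries of that time; these libraries also entered the choice of the genes.

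Edge weights in the authors' deposited table differ between pairs and between targets: 30.3% of pairs have a weight of 0, the 44962 pairs with the highest weight hold 67.0% of all weight, and 10 of the 2294 targets hold 8.4%. A candidate explanation is that weights carry the scale of the expression values, since the summed weight of a target followed its mean quantile normalized value with a Spearman rho of 0.84 over 2294 targets. The summed weight did not rise with the size of the nitrogen response over all targets, with a rho of -0.13 against the absolute effect at 60 to 120 min. With ranks adjusted for the mean value rho was 0.23, so a weak relation among targets of equal mean value stays open. Among 196 regulators the summed weight fell with the mean value, with a rho of -0.72. Genes are not independent replicates, so no p-value is given.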
